A study of Mus musculus with 8 samples.

How the data were processed

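The data are expression values from 8 Affymetrix arrays of mouse trophectoderm, 4 from dams on a control diet and 4 from dams on a high fat diet. Each array held RNA from a pool of 5 blastocysts. Per the labels' protocols, RNA was isolated with the PicoPure kit, and cDNA was amplified with the Ovation PICO WTA system and amplified again with the TransPlex WTA kit. Repeated amplification of small RNA amounts can widen the spread between pools, in particular for dim transcripts. The authors deposited log2 values, and the submitters' processing notes name RMA and Partek without versions. RMA corrects background, normalizes between arrays and summarises probes into probe sets. The array medians still differed between diets in the deposited values. The genome build, the settings of RMA and any test by the authors are not given in the sources used here, so no coordinates are reported.

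The table held 23332 probe sets and 8 columns, each of which was matched to a sample by its label, and 0 columns belonged to other samples. Values ran from 2.67 to 14.69. The platform annotation paired 14996 probe sets with 1 gene symbol and 1019 with several, and 7317 were unnamed here. The 16015 probe sets with at least 1 symbol were tested, and no gene was named from a probe set with several. Symbols were updated by gene ID through a RefSeq table of assembly GRCm38.p6, used for names alone. It held 14941 of the single-symbol probe sets, and 55 kept their older name. For gene lists, 1 probe set per gene was kept, the one with the highest mean, giving 14860 genes.

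The diet groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over 16015 probe sets, threshold 0.05), without a filter on dim probe sets in the main comparison. The replicate number was not used as a block, since nothing in the labels ties equal numbers to a shared litter or day. The 23 gene lists were tested with limma's camera at a preset correlation of 0.01, at least 5 measured members, and Benjamini-Hochberg adjustment over the lists, then with an estimated correlation and with fry. Of 561 list entries, 447 were measured. Percentiles of list medians came from 10000 random lists matched on mean level within 100 genes to either side. Array measures and distances were compared by exact permutation over 70 assignments or 35 splits. The groups, tests, lists, rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added later.

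The genes named were, in each direction, up to 12 single-symbol genes at or above the median level with the largest changes past the threshold, filled by those with the smallest limma p. Gene models without an established name, receptor families and histone clusters were left out. Each list contributed up to 4 members with the smallest limma p. In lists past the threshold 4 were taken and in the others 2, a number set after the data were examined. A further 12 lineage and sex-linked genes were always named, of which 9 were measured under a single symbol (Krt8, Xist and Ddx3y not analysed here). Genes outside this rule are said to be chosen after their values were seen.

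Alternatives changed the probe sets tested, the scaling between arrays (median centring, quantile normalization), the variance model (trend and robust, array weights, no moderation), the replicate block, a Y-linked covariate, the threshold, and left out each array in turn. Cyclic loess, the random lists and the background measure were added after the data were seen. The background was the 95th percentile of 840 chemosensory receptor probe sets of the same array, with the 99th as the other setting. Where high fat diet arrays of a gene lay below it, the bound given is the control diet mean against the mean of the higher of the signal and the percentile on each high fat diet array. Such a bound is for the group means and does not count the spread between pools.

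The tests were run on simulated data for 4 against 4 arrays, with 20 simulations of 16015 probe sets of which 200 were changed by known amounts. Limma at the threshold recovered 10.1% of probe sets changed by 0.5 log2 units, 64.9% of those changed by 1, 87.2% by 2 and 90.2% by 3. Of all calls, 5.67% were false. A list of 20 genes lowered by 0.5 was called in 20 of 20 simulations, and 1 of 440 tests of other lists was called. The simulated genes varied independently, which camera's preset correlation nearly assumes.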

Results

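Gene expression was measured in mouse trophectoderm at embryonic day 4.5, just before implantation. Trophectoderm is the outer epithelium of the blastocyst and gives rise to the placenta. Here it was cut from the abembryonic (mural) side, away from the inner cell mass. The dams were C57BL/6J mice that had eaten a control diet or a high fat diet from weaning until mating at 16 weeks of age. Each sample was a pool of 5 blastocysts hybridised to 1 array, with 4 control diet arrays and 4 high fat diet arrays. The question was whether maternal diet altered the transcriptome of this tissue. The labels call the arrays biological replicates, and which dams supplied each pool is not given in the sources used here, so p-values measure the spread between pools. The values are log2 signals, and the number of arrays limits the precision. Arrays correlated with each other at r between 0.821 and 0.921 over 16015 tested probe sets, so no array duplicated another.

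Usp1, a deubiquitinase that acts in DNA repair, fell in the high fat diet pools. Its log2 signal was 8.32 ± 0.30 (SD, n = 4) with the control diet and 5.26 ± 0.42 (SD, n = 4) with the high fat diet, a measured log2 change of -3.06 with an SE of 0.24. All 4 high fat diet values lay below the 95th percentile of chemosensory receptors on the same array, taken as background, so the change is a bound, at least 3.90-fold lower against that percentile and at least 2.29-fold against the 99th. All 4 high fat diet arrays lay below all 4 control diet arrays. Usp1 (probe set 6915734) was the 1 probe set of 16015 past the limma threshold (adjusted p = 0.032), and 0 probe sets passed it in the higher direction. At an unadjusted limma p under 0.05, 4826 probe sets read higher and 286 lower. Over both directions together this was 5112, against 800.75 expected by chance. Without control diet replicate 1 the higher count was 2870, and without high fat diet replicate 3 the lower count was 184. The call of Usp1 was lost with quantile normalization (adjusted p = 0.061) and with cyclic loess (adjusted p = 0.058), and without high fat diet replicate 3 (adjusted p = 0.13), while its log2 change stayed between -3.36 and -2.85 in all settings run. Leaving out any of control diet replicates 1, 3 and 4 or high fat diet replicates 2 and 4 also ended the call (adjusted p = 0.24, 0.082, 0.15, 0.094 and 0.084 in that order), and over all settings the adjusted p ran from 0.017 to 0.44. Without variance moderation Usp1 had an adjusted p of 0.052 and Dgcr6, at +0.53, was called in its place (adjusted p = 0.039).

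The 11 genes that filled the places after Usp1 in the lower direction did not pass the threshold, each with a limma adjusted p of 0.115. Prpf8, a core protein of the spliceosome, went from 8.80 ± 0.09 to 7.60 ± 0.26 (SD, n = 4 each). Tjp1, the tight junction scaffold, went from 9.18 ± 0.26 to 7.60 ± 0.29. Ndufaf4, an assembly factor of respiratory complex I, went from 9.08 ± 1.26 to 5.29 ± 0.74, with 1 of 4 high fat diet arrays above the receptors' 95th percentile. Nup50 and Kpna3, which act in transport through the nuclear pore, differed by -1.33 and -1.32. The others were Akap8 (-1.61), Foxj3 (-2.10), Ppip5k2 (-1.95), Wdr36 (-1.93), Capn7 (-0.96) and Lta4h (-0.84). On each of these 12 genes every high fat diet array read below every control diet array. They were picked by small limma p, which favours groups that lie apart, so the separation adds no support. Over all 16015 tested probe sets, groups lay apart in the lower direction on 137 and in the higher direction on 4071. For 5 of the 12 genes, Usp1, Capn7, Ppip5k2, Lta4h and Kpna3, no high fat diet array lay above the receptors' 95th percentile, so these differences are not exact. With high fat diet values raised to that percentile they were at least 1.96, 0.30, 1.06, 0.41 and 0.54 log2 units in that order, and against the 99th percentile Capn7, Lta4h and Kpna3 had no bound above 0. Ndufaf4, Wdr36 and Nup50 lay above the 95th percentile on 1, 2 and 3 of 4 high fat diet arrays. Their differences are therefore not exact either. They were at least 2.72, 1.63 and 1.32 log2 units against it, and 1.96, 1.01 and 1.09 against the 99th.

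The 12 genes named in the higher direction did not pass the threshold (limma adjusted p = 0.115 for each). Dnajc30, a mitochondrial co-chaperone, went from 6.71 ± 0.08 to 7.46 ± 0.13 (SD, n = 4 each), and Clps, the pancreatic colipase, from 6.17 ± 0.05 to 6.85 ± 0.09. The other 10 genes named for this direction were Cdpf1, Dgcr6, Prss50, Lhx2, Tsnax, Gng4, Elane, Fam167b, Sstr3 and Odf3. Their log2 changes ran from +0.52 for Gng4 to +0.69 for Tsnax. Prss50 and Odf3 are known from testis and sperm, and Elane from neutrophils. Prss50, Odf3 and Lhx2 lay above the receptors' 95th percentile on 0, 0 and 1 of 4 control diet arrays and on 2, 1 and 3 of 4 high fat diet arrays, so their differences are measured near the background. Relative to the median change of all tested probe sets, these differences ran from +0.30 for Gng4 to +0.53 for Dnajc30. Pdlim1, a cytoskeletal adaptor, and Zfp296, a zinc finger protein, were chosen after their values were seen. Pdlim1 went from 9.01 ± 0.74 to 11.31 ± 0.30 and Zfp296 from 6.14 ± 0.35 to 8.12 ± 0.68 (SD, n = 4 each), with groups apart on both and a limma adjusted p of 0.115 for each. Groups lay apart in the higher direction on 4071 of all 16015 tested probe sets, so this does not mark these genes out.

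**Figure D1:**
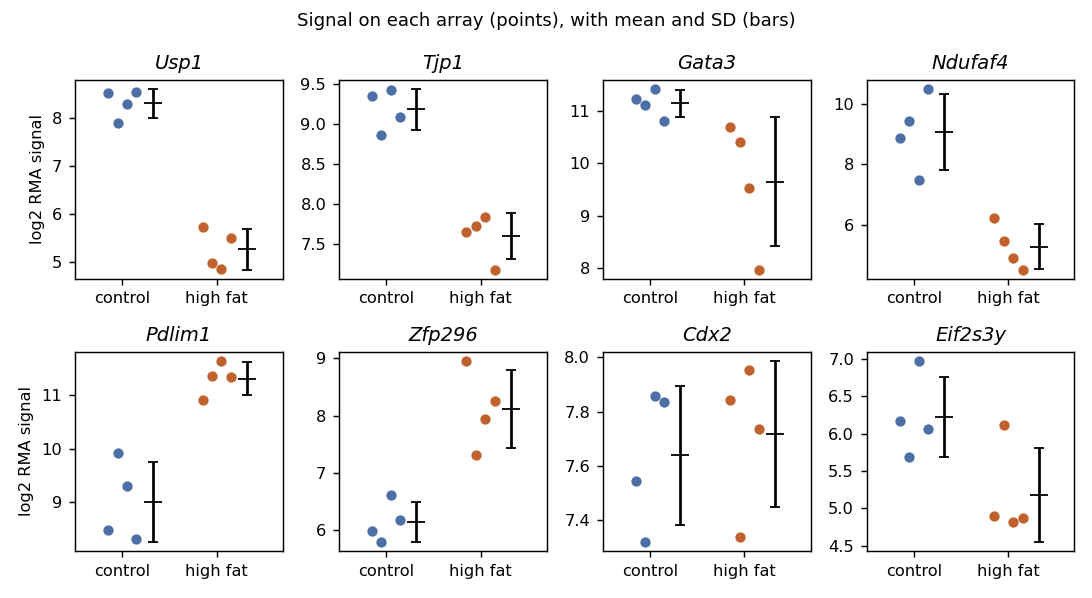
Log2 RMA signal of 8 genes on each array, with points for the 4 control diet and 4 high fat diet arrays and bars for mean and SD. Each panel has its own range that does not start at 0. Usp1 separates at 8.32 against 5.26, while Cdx2 overlaps at 7.64 against 7.72.

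The high fat diet arrays read higher over most of the signal range. The median log2 change of the tested probe sets was +0.22, and 78.7% of them had a change above 0. Chemosensory receptors, families known from sensory neurons, shifted by +0.20 over 840 probe sets, and probe sets without a gene name by +0.15. The brightest 10% went the other way, with a median of -0.16. Among probe sets at an unadjusted p under 0.05, 94.4% read higher, against 67.3% after median centring, 76.8% after quantile normalization and 44.1% after cyclic loess. The array medians were 5.65 ± 0.05 with the control diet and 5.83 ± 0.09 with the high fat diet (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible, adjusted to 0.067 over 7 array measures). Fewer probe sets lay above the 95th percentile of the receptors, 6262.5 ± 284 against 5465 ± 633 (SD, n = 4 each; exact permutation p = 0.086, adjusted to 0.1 over 7 array measures). The difference of -797.25 was -529 without high fat diet replicate 3 (exact permutation p = 0.11). High fat diet replicate 3 had the lowest number, 4661, and the lowest mean correlation with the other arrays, 0.832 against 0.879 to 0.890 elsewhere. Of the 88 genes named here, 20 lay above the receptors' 95th percentile on no array. They were Esx1, Plac8, Mmp9, Esrrb, Sox2, Calb1, Cd74, Lss, Thrsp, Lipg, Lpl, Pdk4, Ppara, Hk1, Pfkm, Tsc1, Rtl1, Itga7, Egfr and Kdm5d. The differences below are measured values without subtraction of the median of +0.22 unless said.

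**Figure D2:**
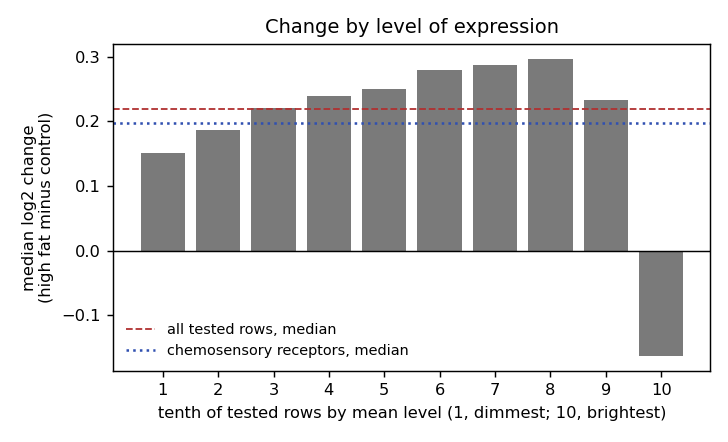
Median log2 change (high fat minus control) of tested probe sets in 10 equal bins by mean level, from the dimmest at 1 to the brightest at 10. The dashed line is the median of all tested probe sets (+0.22) and the dotted line that of the chemosensory receptors (+0.20). Medians are above 0 in bins 1 to 9 and at -0.16 in the brightest, with high fat diet replicate 3 included.

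Genes of DNA and histone methylation fell as a group relative to other genes. Of the 20 measured members, 19 lay below the median change of all tested probe sets and 13 below 0, and the median log2 change was -0.15, or -0.37 relative to all tested probe sets. An exact permutation test of the mean of its members per array gave p = 0.0286, the smallest possible, adjusted to 0.22 over the 23 lists. The median lay at the 1.32nd percentile of random lists of the same level. Limma's camera gave an adjusted p of 4.2e-06 with its preset correlation and an adjusted p of 0.029 with an estimated correlation. Uhrf1, which brings the maintenance DNA methyltransferase to replicated DNA, went from 7.91 ± 1.19 to 6.20 ± 0.54 (SD, n = 4 each), and Eed, of the Polycomb complex that methylates histone H3, from 10.09 ± 0.19 to 8.92 ± 0.77. Uhrf1 lay above the receptors' 95th percentile on 2 of 4 high fat diet arrays. Its group means differed by at least 1.48 log2 units against that percentile and 0.79 against the 99th. The groups overlapped, and the measured change had an SE of 0.58. Kdm6a, a histone demethylase, read at 5.81 ± 0.62 and 5.03 ± 0.23, above the receptors' 95th percentile on 2 of 4 control diet and 0 of 4 high fat diet arrays, so its difference is measured at the background. Tet3, which oxidises methylated cytosine, read higher at 6.65 ± 0.29 against 6.17 ± 0.17. None of the 20 members passed adjusted over the list alone or over all genes tested. The list passed after quantile normalization (adjusted p = 0.0014), but not with an estimated correlation on those values (adjusted p = 0.11). Without high fat diet replicate 3 the adjusted p was 2.7e-05, and with an estimated correlation the adjusted p was 0.12.

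**Figure D3:**
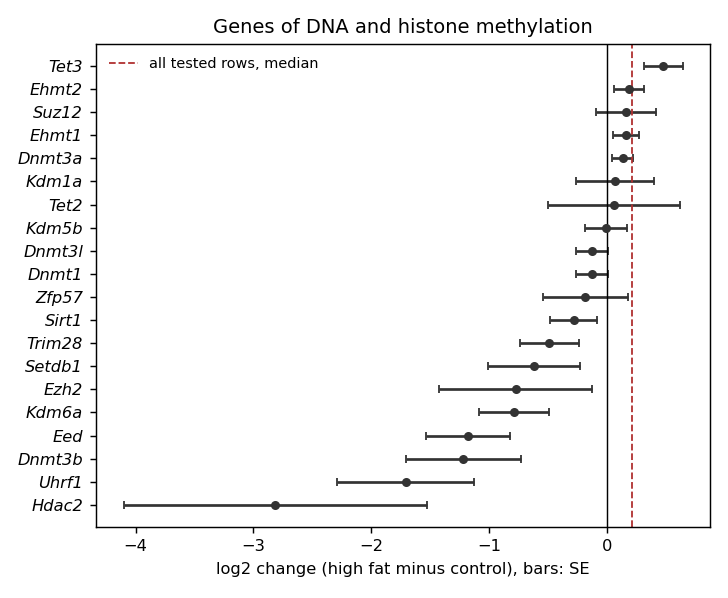
Log2 change (high fat minus control) of the 20 measured genes of DNA and histone methylation, with SE as bars. The dashed line is the median of all tested probe sets (+0.22). 19 of the 20 points lie to its left and 13 lie below 0.

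Genes of epithelial junctions, the blastocoel and attachment fell relative to other genes (camera adjusted p = 0.0061). The call was lost with an estimated correlation (adjusted p = 0.35) and with quantile normalization (adjusted p = 0.54), and without high fat diet replicate 4 (adjusted p = 0.076). Of 26 measured members, 19 lay below the median change of all genes, and the median was +0.02, above 0, while the mean was -0.15. That median lay at the 9.17th percentile of random lists of the same level. Adjusted over the list alone, 1 member fell, Tjp1, which also passed with quantile normalization and with cyclic loess. The integrin subunit Itga7 (+0.46) passed over the list alone too, with neither scaling, and lay above the receptors' 95th percentile on 0 of 8 arrays, so no rise is read from it. Over all genes tested, 0 members passed. Itgb1, an integrin subunit, read at 10.28 ± 0.22 against 10.73 ± 0.25 (SD, n = 4 each), and Egfr at 5.06 ± 0.13 against 4.79 ± 0.11. Egfr also lay above the receptors' 95th percentile on 0 of 8 arrays, so no rise is read from it either.

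Genes of the unfolded protein response fell relative to other genes (camera adjusted p = 0.048), a call lost with an estimated correlation (adjusted p = 0.73). It was also lost with quantile normalization (adjusted p = 0.61) and without high fat diet replicate 3 (adjusted p = 0.13). Leaving out control diet replicate 2 or 4 (adjusted p = 0.30 and 0.066) or high fat diet replicate 1 or 4 (adjusted p = 0.13 and 0.087) ended it too. The 22 measured members were split, 12 below and 10 above the median change of all genes, and their median of +0.04, at the 5.89th percentile of random lists of the same level, was above 0 while the test was in the lower direction. The chaperone Pdia6 read lower (log2 change -1.27), and the stress-response genes Chac1 (+0.51) and Atf3 (+0.43) higher. Dnajb9, another chaperone, differed by -1.63 but lay above the receptors' 95th percentile on 0 of 4 high fat diet arrays. The group means of Dnajb9 differed by at least 0.22 against that percentile, with no bound above 0 against the 99th. The groups overlapped, and the measured change had an SE of 0.51. None of the 22 passed adjusted over the list alone or over all genes tested.

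Krt18, a keratin of the trophectoderm, read at 12.27 ± 0.70 with the control diet and 12.69 ± 0.19 with the high fat diet (SD, n = 4 each). Cdx2, the lineage transcription factor, read at 7.64 ± 0.26 and 7.72 ± 0.27, and Eomes at 8.04 ± 0.55 and 8.18 ± 0.54; these differences were smaller than the spread between pools, and the sign turned to lower with median centring for both and with cyclic loess for Cdx2. Gata3, another lineage factor, read at 9.65 ± 1.22 against 11.14 ± 0.26, and Fgfr2, a receptor for fibroblast growth factor, at 7.41 ± 0.60 against 9.18 ± 0.95. Neither passed (limma adjusted p = 0.13 and 0.115). The difference of Gata3, -1.49, was -0.93 without high fat diet replicate 4, and that of Krt18, +0.42, was +0.13 without control diet replicate 4. Esx1, a placental homeobox gene, differed by +0.24, and by -0.02 with cyclic loess. The 17 measured members of the trophectoderm list did not shift as a group (camera adjusted p = 0.28), nor did the 16 of mural trophectoderm and giant cells (camera adjusted p = 0.90), among them Plac8 (+0.45) and Mmp9 (+0.37). In these lists 0 members passed adjusted over the list alone or over all genes tested.

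Markers of other cell types that a dissected piece could hold did not pass as groups relative to other genes. The test compares diets over all pools, so it cannot show whether a single pool held such cells. The mean of the inner cell mass members, each centred over the 8 arrays, ran from -0.54 to +0.40 over control diet pools. Over high fat diet pools it ran from -0.10 to +0.38. Pools of the same diet thus differed in these markers, and which cells a pool held was not tested. Camera gave an adjusted p of 0.90 for the inner cell mass and epiblast, 0.90 for primitive endoderm, 0.31 for uterine epithelium and stroma and 0.28 for blood and immune cells. On the mean of the members per array, which holds the array shift, blood and immune cells differed by +0.38 (exact permutation p = 0.0286, adjusted to 0.22 over the 23 lists). The imprinted genes differed by +0.23 with the same exact p. In the blood list the median change of the members was +0.26. Its largest change, +2.01, came from 1 member with overlapping groups and an SD of 2.59 over the high fat diet arrays. Nanog, a pluripotency factor, read at 6.89 ± 0.60 against 7.34 ± 1.14 (SD, n = 4 each), Pou5f1 at 9.01 ± 0.68 against 8.94 ± 2.06 and Sox2 at 4.50 ± 0.28 against 4.43 ± 0.50, and the sign of the Pou5f1 and Sox2 differences turned with median centring. The difference of Nanog, -0.45, ran from -0.83 to -0.10 with an array left out. In the inner cell mass list Klf2 (+0.64) passed adjusted over the list alone and Esrrb (+0.35) did not pass. The endoderm factors Gata4 and Gata6 differed by +0.25 and +0.31, Col4a1 by +0.45 and Hnf4a by +0.44. Col1a1 and Calb1 of the uterine list differed by +0.55 and +0.28, and Cd74 and Cx3cr1 of the blood list by +0.36 and +0.27. With cyclic loess Gata4 differed by -0.05 and Cx3cr1 by -0.03. Adjusted over the list alone, 4 of 18 primitive endoderm genes, 2 of 15 blood and immune genes, 1 of 18 inner cell mass genes and 0 of 20 uterine genes passed in the higher direction, against 0 over all genes tested. Cd74, 1 of the 2 blood genes, lay above the receptors' 95th percentile on 0 of 8 arrays. With cyclic loess 0 members of these lists passed.

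No list of lipid or energy metabolism passed camera in the main setting, though the median of oxidative phosphorylation was high for its level. Camera gave adjusted p-values of 0.41 for cholesterol synthesis, 0.90 for fatty acid synthesis, 0.90 for lipid uptake and storage, and 0.36 for fatty acid oxidation and PPAR targets. The adjusted p was 0.11 for oxidative phosphorylation, 0.90 for glycolysis and glucose transport, and 0.41 for insulin and mTOR signalling with amino acid transport. Oxidative phosphorylation passed in the lower direction without high fat diet replicate 1 (adjusted p = 0.047), while its median of +0.25 lay at the 99.4th percentile of random lists of the same level and the direction turned to higher with cyclic loess (adjusted p = 0.12). Srebf2, the transcription factor of cholesterol synthesis, read at 8.22 ± 0.41 against 7.53 ± 0.33 (SD, n = 4 each), and Lss of the same pathway differed by +0.35. Pnpla3 and Thrsp differed by +0.50 and +0.48, Lipg and Lpl by +0.51 and +0.29, and Pdk4 and Ppara by +0.30 and +0.23, the last turning to -0.02 with cyclic loess. Cyc1 and Ndufa5 of the respiratory chain read higher by +1.22 and +1.31, and Akt1 and Tsc1 by +0.48 and +0.28. Adjusted over the list alone, 6 of 16 glycolysis genes passed in the higher direction. Among them Hk1 (+0.44) and Pfkm (+0.54) lay above the receptors' 95th percentile on 0 of 8 arrays, so these differences are of background signal, and 0 members of the other lists of this paragraph passed. The differences of Lss, Thrsp, Lipg, Lpl, Pdk4, Ppara and Tsc1 are of background signal too, with 0 of 8 arrays above it. With quantile normalization 1 glycolysis gene passed over the list alone, and with cyclic loess 0 did. Over all genes tested, 0 members passed.

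The remaining lists did not pass either. Camera gave an adjusted p of 0.056 for the cell cycle, where 20 of 27 genes lay below the median of all genes and Aurkb (+0.54) and Tyms (+0.48) above it. The cell cycle list passed in the lower direction without control diet replicate 1 (adjusted p = 0.011), control diet replicate 3 (adjusted p = 0.018) or high fat diet replicate 4 (adjusted p = 0.0039). The adjusted p was 0.90 for oxidative stress, 0.90 for inflammation and the interferon response, 0.90 for apoptosis and p53 targets, 0.90 for imprinted genes, 0.90 for ribosomal proteins, and 0.59 for immediate early and heat shock genes. Members with the smallest limma p included Gstm1 (+0.75) and the metallothionein Mt1 (+0.75) of oxidative stress, Cxcl1 (+0.53) and Socs3 (+0.46) of inflammation, Phlda3 (+0.31) and Bbc3 (+0.37) of apoptosis, Ndn (+0.61) and Rtl1 (+0.47) of imprinting, Rpl10a (+0.62) and Rps3 (+0.45, and +0.29 without high fat diet replicate 3) of the ribosome, and Ier3 (+0.70) and Jund (+0.60) of the early response. Adjusted over the list alone, 1 oxidative stress, 2 inflammation, 4 apoptosis, 1 imprinted, 1 ribosomal and 2 early response genes passed in the higher direction and 0 cell cycle genes passed. Over all genes tested 0 passed. Of 25 such list members that passed in the higher direction over all 23 lists, 4 passed with quantile normalization and 0 with cyclic loess. In 7 of the 23 lists the median relative to all genes and the camera direction differed in sign, and in 5 the median and the mean did.

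The mean of the Y-linked genes, which report male embryos in a pool, read lower with the high fat diet, through Eif2s3y alone. Of the 4 listed, 2 were measured, Eif2s3y and Kdm5d. Their mean per array was 5.24 ± 0.31 with the control diet and 4.74 ± 0.31 with the high fat diet (SD, n = 4 each). The exact two-sided permutation p was 0.086, adjusted to 0.1 over 7 array measures. Eif2s3y read at 6.22 ± 0.54 and 5.18 ± 0.63, with high fat diet replicate 2 at 6.11 and the other high fat diet arrays between 4.82 and 4.90. It lay above the receptors' 95th percentile on 2 of 4 control diet arrays and 0 of 4 high fat diet arrays, so its difference is measured at the background. Kdm5d read at 4.27 ± 0.10 and 4.30 ± 0.07, below the receptors' 95th percentile of 6.17, and its sign turned with quantile normalization. The test of the mean was fixed before the data were examined. Giving the 2 genes singly was chosen after their values were seen, as the rule for named genes held Ddx3y alone.

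Arrays of different diets were farther apart than arrays of the same diet. The mean Euclidean distance was 108.0 between diets and 102.5 within a diet, a difference of 5.52 (exact one-sided permutation p = 0.0286 over 35 splits, the smallest possible). High fat diet replicates 1, 2 and 4 correlated on average at r = 0.892, 0.899 and 0.884 with control diet arrays. With arrays of their own diet r was 0.878, 0.878 and 0.872. The own-diet averages include high fat diet replicate 3, whose average with its own diet was 0.845, and the averages with control diet arrays do not. A closer match to control diet arrays is therefore not read from these values. Within a diet the mean distance was 97.4 for control diet arrays and 107.5 for high fat diet arrays. Over the 1000 most variable probe sets the difference was 1.58 (exact p = 0.14), and without high fat diet replicate 3 it was 3.41 (exact p = 0.086). Without each control diet array, or without high fat diet replicate 1, the exact p was between 0.057 and 0.17.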

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

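The tests of the background shift, of the array that stood apart, of the receptor share, of cyclic loess and of Kdm5d, and the bounds and the sizes of the methylation change, were chosen after their results were seen.

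Most probe sets read higher on the high fat diet arrays. A shift of background after RMA is a candidate explanation: the chemosensory receptors, which trophectoderm is not known to use, shifted by 0.198 against 0.218 for all tested probe sets. An effect of diet on each gene's own transcription is argued against as the whole cause, since 86.3% of the receptor probe sets read higher, and so is high fat diet replicate 3 alone, since the median change without it was 0.165. Of the 35 splits of the 8 arrays, 1, the real one, gave as many as 5112 probe sets at an unadjusted p under 0.05. The highest other gave 2568. As 1 of 35 is the smallest share possible, this argues against chance without excluding it. The array medians had an exact permutation p adjusted to 0.067 over 7 array measures. Whether the shift came from RNA amount, amplification or diet stays open, as diet and handling were not varied separately.

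Genes of DNA and histone methylation read lower than other genes. Camera at its preset correlation still called the list when 3 technical explanations were tested as the whole cause. For a level-dependent shift the adjusted p was 0.000226, after cyclic loess. For high fat diet replicate 3 alone it was 2.66e-05, without that array. For fewer probe sets above background it was 0.000849, with their number as a covariate. Splits other than the real one also gave small p-values at this setting, so these calls cannot decide against the explanations. With each correction the size given below stayed in the lower direction. The list was picked as the smallest p of 23 on these same arrays, so a size that persists does not decide either. The number of probe sets above background also goes with diet, and the estimate with it as a covariate has the widest SE. With an estimated correlation the adjusted p-values were 0.109, 0.121 and 0.147, while the change of the members' mean against the median of all genes was -0.55 ± 0.12, -0.56 ± 0.15 and -0.55 ± 0.21 (SE), against -0.63 ± 0.15 uncorrected and -0.49 ± 0.13 with quantile normalization, which moved it most. For this list alone 1 of 35 splits gave a p as small as 1.83e-07, with 7.07e-07 in the nearest other, but it was the smallest of 23 lists, and over all lists 3 of 35 splits had a smallest p as small, with 2.55e-10 in the highest other, so chance cannot be excluded. Lower levels of these transcripts may be followed up as a hypothesis, and diet stays untested against dam or litter.

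Eif2s3y read below every control diet pool in 3 of 4 high fat diet pools. Its mean level of 5.70 lay below the receptors' 95th percentile of 6.17, so the tests on it decide little. Of the 200 probe sets nearest in level 1.5% were lower by as much, but at that background a general loss of expressed genes stays open. Fewer male embryos in those pools could account for it, and the other Y-linked gene, Kdm5d, cannot decide, as its change of 0.031 lay at the receptor background. An effect of diet on Eif2s3y itself and chance in pools of 5 embryos stay open.

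Among 236 groups of 4 arrays, 12 had 1 array far from the other 3, against 11.8 expected by chance. High fat diet replicate 2 had the higher Y-linked mean (5.20) and Eif2s3y (6.11), and a low Srebf2 (7.61). High fat diet replicate 3 was high for Tsnax (7.65) and Col1a1 (8.23), and replicate 4 was low for Gata4 (6.77) and high in the fatty acid synthesis score (0.241). Control diet replicate 1 was high for Capn7 (6.999) and low for Ppara (5.33), replicate 3 was low for Nup50 (7.84) and high in the imprinted gene score (-0.043), and replicate 4 was high for Srebf2 (8.02).

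Of the probe sets without a gene name, which no test of single genes above used, 2 passed the limma threshold when all probe sets were tested. Probe set 5204795 read at 10.80 ± 0.49 with the control diet and 5.27 ± 0.59 with the high fat diet (SD, n = 4 each), a log2 change of -5.53 (adjusted p = 0.014). Probe set 5475033 read at 9.65 ± 1.04 and 3.35 ± 0.46, a log2 change of -6.30 (adjusted p = 0.028). Both lay below the receptors' 95th percentile on all 4 high fat diet arrays, so the sizes of these changes are bounds, at least 4.45 and 3.30 log2 units.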

How the results depend on the processing

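Cyclic loess, the background percentiles, the counts at an unadjusted p and the bound for Usp1 were added after the data were seen. That bound, 1.96 log2 units against the receptors' 95th percentile, was 1.20 against the 99th and 1.89 to 2.10 with an array left out. Where a result moved, the cause was not tested unless stated. Of the results for named genes, 1696 alternatives kept direction and side of the threshold, 30 turned direction, 11 lost a call and 2 gained a call. For lists these counts were 281, 59, 18 and 10. A gene or list without a call counts as kept while it stays uncalled with the same sign. Several settings also leave the log2 change as it was, so these counts are no measure of support. The Y-linked mean stayed lower and short of the threshold in all 10 alternatives run, and Xist in its place was not run, as no probe set names it. Signal over background limits dim genes, where a sign can turn with scaling alone.

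The count of called probe sets, 1 in the main setting, was 0 with quantile normalization, cyclic loess and the Y-linked covariate, 3 with all probe sets (Usp1 and 2 without a name), 556 at an unadjusted p under 0.05 and 1.5-fold (316 higher, 240 lower), and between 0 and 2 when each array was left out. Without variance moderation it stayed 1, but the gene was Dgcr6 (adjusted p = 0.039) and not Usp1 (adjusted p = 0.052). Leaving out high fat diet replicate 1 added Kif1c, chosen after its values were seen, and leaving out control diet replicate 2 added Akap8. With the replicate block the count was 0. Same-numbered arrays deviated together at r of 0.033, -0.019, 0.012 and 0.084, and 1 of 4 control diet arrays correlated best with its own number. These 4 pairs cannot settle whether equal numbers shared a litter or day. The block left the list count at 3 and turned fatty acid synthesis to higher (adjusted p = 0.978). Higher counts at an unadjusted p, 4826 in the main setting, were 2146 in the brighter 50% of probe sets, 1390 with median centring, 1599 with quantile normalization, 656 with cyclic loess, 1094 with the Y-linked covariate and 2870 to 5420 with an array left out. Lower counts, 286 in the main setting, were 676, 482 and 832 with those 3 scalings, 185 without moderation and 184 to 380 with an array left out. Probe sets above the receptors' 99th percentile differed by -792.5 (exact permutation p = 0.0286, adjusted to 0.067 over 7 array measures), against -797.25 at the 95th. Without high fat diet replicate 3 the difference at the 99th was -631 (exact permutation p = 0.057). The between-diet minus within-diet distance was 1.58 over the most variable probe sets and 3.11 to 9.40 with an array left out.

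The count of lists, 3 in the main setting, was 1 with an estimated correlation, median centring, quantile normalization and cyclic loess, and 9 with fry, which asks whether genes move one way without comparing them with other genes. The adjusted p of the unfolded protein response was 0.728 with an estimated correlation, 0.519 in the brighter genes, 0.509 with median centring, 0.611 with quantile normalization, 0.424 with the Y-linked covariate, 0.560 with cyclic loess, and 0.0068 to 0.298 with an array left out. That of epithelial junctions was 0.354, 0.0753 (median centring), 0.543 (quantile), 0.657 (covariate), 0.396 (loess) and 0.00048 to 0.0755 with an array left out. With 1 choice changed at a time, DNA and histone methylation passed in all settings except fry (adjusted p = 0.0601). With an estimated correlation it did not pass on quantile-normalized (adjusted p = 0.109) or cyclic loess values (adjusted p = 0.109), without high fat diet replicate 3 (adjusted p = 0.121) or with the background covariate (adjusted p = 0.147). Oxidative phosphorylation passed without high fat diet replicate 1 (adjusted p = 0.0469). The cell cycle list passed with the Y-linked covariate (adjusted p = 0.0049) and without control diet replicate 1 (0.0114), control diet replicate 3 (0.0175) or high fat diet replicate 4 (0.0039).

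Lists that turned direction are given by adjusted p. With fry, which carries the array shift, these turned to higher: trophectoderm and cholesterol synthesis (0.249 each), inner cell mass (0.0605), primitive endoderm and insulin signalling (0.0601 each), fatty acid synthesis (0.0650), fatty acid oxidation and oxidative stress (0.0477 each), oxidative phosphorylation (0.101), unfolded protein response (0.530), apoptosis and ribosomal proteins (0.0460 each), cell cycle (0.541) and junctions (0.903). In the brighter genes these turned: mural trophectoderm (0.674), inner cell mass (0.735), lipid uptake (0.896), oxidative stress, inflammation and apoptosis (0.944 each) and ribosomal proteins (0.990). With median centring these turned: inner cell mass (0.825), primitive endoderm (0.970), fatty acid synthesis and oxidative stress (0.666 each), lipid uptake, apoptosis and ribosomal proteins (0.941 each). With quantile normalization these turned: inner cell mass, primitive endoderm, fatty acid synthesis, oxidative phosphorylation, apoptosis and ribosomal proteins (0.887 each) and oxidative stress (0.802). With the covariate insulin signalling (0.918) and apoptosis (0.464) turned. With cyclic loess these turned: inner cell mass (0.560), fatty acid synthesis (0.953), oxidative phosphorylation (0.117), oxidative stress (0.179) and ribosomal proteins (0.275). With an array left out some turned, over ranges of 0.648 to 0.990 for mural trophectoderm, 0.458 to 0.990 for inner cell mass, 0.648 to 0.954 for primitive endoderm, 0.717 to 0.966 for fatty acid synthesis, 0.717 to 0.957 for lipid uptake, 0.604 to 0.986 for oxidative stress, 0.869 to 0.954 for apoptosis and 0.717 to 0.960 for imprinted genes.

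The log2 changes of some genes turned to lower. With median centring they were Cdx2 (-0.107), Eomes (-0.0509), Pou5f1 (-0.112), Sox2 (-0.121) and Kdm5d (-0.155). With quantile normalization they were Sox2 (-0.107) and Kdm5d (-0.137), and with array weights Sox2 (-0.0427). With the covariate they were Eomes (-0.044), Pou5f1 (-1.11) and Sox2 (-0.334). With cyclic loess they were Esx1 (-0.0204), Cx3cr1 (-0.0308), Ppara (-0.0207), Cdx2 (-0.102), Sox2 (-0.126), Gata4 (-0.0455) and Kdm5d (-0.150). With an array left out the changes ran from -0.0275 to 0.205 for Cdx2, -0.0882 to 0.373 for Eomes, -0.567 to 1.00 for Pou5f1, -0.092 to 0.239 for Sox2 and -0.0134 to 0.0643 for Kdm5d.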

Other observations

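Of 10 protein families set by symbol after the data were seen, 8 read lower than other genes in the high fat diet pools at camera's threshold. They hold genes already seen to be low, so their p-values are not independent of those values. These were Prpf8 among splicing factors, Nup50 and Kpna3 among nucleoporins with importins, Usp1 among ubiquitin-specific proteases and Kif1c among kinesins. Nucleoporins with importins (39 genes) had a median log2 change of -0.22, and 33 of them lay below the median of all genes. Translation initiation factors (36 genes) had a median of -0.32, and splicing factors (73 genes) of -0.11. Camera adjusted p-values over 10 families were 1.5e-08, 1.2e-07 and 7.6e-09, and 8 of the 10 families passed. Zinc finger proteins (208 genes, adjusted p = 0.52) and Rab GTPases (51 genes, adjusted p = 0.25) did not pass. Against random lists of the same level the order differed: zinc finger proteins lay at the 0.04th percentile, while mitochondrial ribosomal proteins (50.87) and proteasome subunits (16.7), which passed, were not extreme. With an estimated correlation 5 families passed, with cyclic loess 4, and with both 0.

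A hypothesis was that families of nuclear proteins were lower as the DNA and histone methylation genes were. After cyclic loess, nucleoporins with importins passed (adjusted p = 7.4e-05) and splicing factors did not (adjusted p = 0.0507), so the test left it undecided. Of the 35 splits of the arrays, 4 gave as many as 8 families past the threshold, and the highest other gave 8, so chance cannot be excluded for this count.

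The same count for single probe sets and lists gave a like picture. Of the 35 splits, 4 gave at least 1 called probe set, with 1 for the real split and 2 for the highest other. For the lists, 10 splits gave at least 3, with 3 for the real split and 6 for the highest other. Chance can be excluded for neither count.

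Kif1c, a kinesin chosen after its values were seen, read at 11.52 ± 0.69 with the control diet and 6.09 ± 2.69 with the high fat diet (SD, n = 4 each). High fat diet replicate 1 lay at 10.06 and the other high fat diet arrays between 4.26 and 5.39, below the receptors' 95th percentile. The difference of the means is therefore a bound, at least 4.20 log2 units against that percentile and 3.63 against the 99th.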
